A study of Homo sapiens with 6 samples.

How the data were processed

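RNA sequencing libraries of HCT116, an established human colorectal cancer cell line, were compared between 3 control libraries and 3 libraries labelled ZFP90 knockout. Per the labels' protocols, guide RNAs targeted exon 3 of ZFP90, cells were at passage 16 to 19, and libraries were made from 1 µg of total RNA with an Illumina TruSeq RNA kit. The labels do not say whether the replicates of a group came from separate cultures or clones, so p-values measure only the spread between these libraries, which may be technical.

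The deposited values are raw read counts per gene symbol, 1 table per library. Per the submitters' processing notes, the tools named were TopHat2 2.0.11 and HTSeq, with the human builds hg19 and GRCh37; the HTSeq version and its strand setting are not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be told apart, and genes with near-identical copies (such as HSPA1B and the HLA genes) are uncertain. Each table listed 56638 gene symbols and 5 summary lines. The summary lines (reads outside genes, ambiguous, not uniquely aligned and similar) held between 31.7% and 32.37% of all listed reads and stayed out of library sizes and tests.

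Reads in genes numbered between 13424356 and 17012910 per library, so 3 reads corresponded to between 0.176 and 0.224 CPM by library size before TMM scaling; such floors and intervals cover counting error only. Counts were tested with edgeR 4.0.16 under R 4.3.3, using the quasi-likelihood test, TMM scaling and the filterByExpr defaults (minimum count 10, minimum total 15), which kept 16369 genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. CPM values in the text were computed from the deposited counts with TMM-scaled library sizes, and log2 fold changes are the libraries labelled knockout over control. All 34 gene lists were fixed before the data were examined; the 33 with at least 5 tested members were tested with camera at its preset correlation of 0.01, two-sided, and again with an estimated correlation and with fry (limma 3.58.1). Older symbols were matched through RefSeq synonyms for 6 list members.

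The genes named were chosen by a rule fixed before the data were examined. It took ZFP90; the 12 largest rises and 12 largest falls among called genes whose libraries did not overlap between groups and whose mean was at least 5 CPM in the higher group, without clone-style names, Y-linked genes and XIST; up to 4 called members of each list with the smallest p, or the most abundant member where none was called; and all tested neighbours of ZFP90. Genes counted under each part that named them. Some genes that the rule takes are not reported here.

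Positions came from GENCODE release 29 on GRCh38 and were used only to place genes by symbol, since the counts were made on another build; 83.7% of tested genes were placed. No replicate pair had counts within sampling noise of each other: the chi-square per degree of freedom ran from 2.2 to 19.8. Control replicate 2 stood apart along the genome. Its effect on each count was computed by leaving it out, by correcting its counts with a running median over 51 genes, and by keeping only the 18 chromosomes without the deficit; the correction and the restriction to 18 chromosomes were chosen after seeing the data. The other alternatives were 3 other scalings, DESeq2 1.42.0, limma-voom, 2 other filters on low counts, the replicate number as a block, an adjusted p under 0.01, and leaving out each library.

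The test was tested on simulated data for the same comparison (16173 genes tested). Of 200 genes seeded with a change, 67, 66 and 60 passed the count filter at 1.5-fold, 2-fold and 4-fold. It recovered 64.2% of these at 1.5-fold, 80.3% at 2-fold and 98.3% at 4-fold, with 4.91% of its calls false. The simulated genes varied independently, without the deficit of control replicate 2, and fewer were changed than were called in the real data. These shares therefore need not hold for the real calls.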

Results

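RNA sequencing of HCT116 colorectal cancer cells gave gene counts for 3 control libraries and 3 libraries labelled ZFP90 knockout. ZFP90 is a zinc-finger protein of the KRAB family, and the series title places the comparison in colorectal carcinogenesis and stemness. Reads in genes numbered 16215490, 14225911 and 13424356 in control replicates 1 to 3 and 17012910, 14450905 and 15623217 in the libraries labelled knockout.

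ZFP90 RNA was higher, not lower, in the libraries labelled ZFP90 knockout. It measured 46.0 ± 2.53 CPM in the controls and 85.7 ± 4.75 CPM in the libraries labelled knockout (SD, n = 3 each), from 770, 720 and 577 reads against 1438, 1135 and 1372 reads. The log2 fold change was 0.90 (SE 0.066; edgeR quasi-likelihood test, adjusted p = 5.1e-05). ZFP90 lies on chromosome 16 from 68530090 to 68576072 on the plus strand (GRCh38, GENCODE release 29). The guide RNAs targeted exon 3, and gene-level counts do not show whether the reading frame was disrupted. A small insertion or deletion in exon 3 need not lower the count, so higher RNA does not by itself contradict the label. Because RNA of the targeted gene rose, directions below are given for the libraries as labelled.

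**Figure D1:**
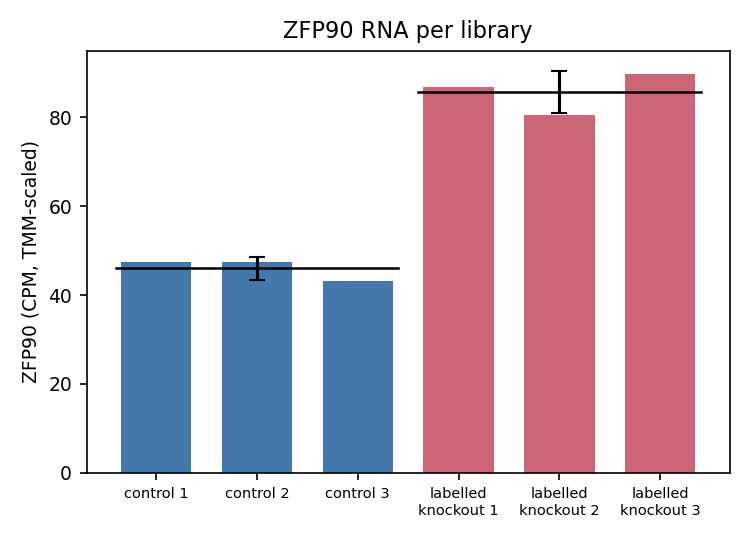
ZFP90 level in CPM (TMM-scaled, vertical axis) in each of the 6 libraries; bars are libraries, and lines with error bars are group means ± SD (n = 3). All 3 libraries labelled knockout, from 80.5 to 89.8 CPM, lie above all 3 controls, from 43.1 to 47.5 CPM.

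Of the 19 tested neighbours of ZFP90 on chromosome 16, 4 rose and 2 fell, with the same counts adjusted over the list alone, and the median log2 fold change was 0.034. HAS3, a hyaluronan synthase, rose by 0.71 (SE 0.053), SNTB2 rose by 0.34 and the amino acid transporter SLC7A6 fell by 0.63. The fall of SMPD3 did not hold with any 1 of the 6 libraries left out (edgeR adjusted p from 0.0538 to 0.145) nor with DESeq2 (adjusted p = 0.0513). The calls of CHTF8 and TERF2 did not hold without control replicate 1 or 3 or without replicate 1 or 3 labelled knockout, where the highest adjusted p was 0.0809 and 0.0955. With 1 library left out at a time, 2 to 4 neighbours were higher and 1 was lower. With control replicate 2 corrected along the genome, 4 were higher and 4 lower. ESRP2 and CDH3 were then called lower (edgeR adjusted p = 0.0259 and 0.0311). CDH1, which encodes E-cadherin, had a log2 fold change of 0.02 (SE 0.046; adjusted p = 0.755).

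BMP4, a secreted bone morphogenetic protein, rose from 24.6 ± 3.45 to 379 ± 68.0 CPM (SD, n = 3; log2 fold change 3.95, SE 0.15; adjusted p = 3.18e-06). The axon guidance ligand SEMA3A rose from 10.3 ± 2.91 to 109 ± 9.33 CPM and the annexin ANXA10 from 15.02 ± 2.33 to 129 ± 4.46 CPM. KRT13, EPS8L3, STK32A, LRP1B, EPGN and P2RX7 rose by log2 fold changes between 2.51 and 3.75. On chromosome X, CAPN6 and MBNL3 rose by 5.94 and 2.70, and by 5.55 and 2.38 without control replicate 2. ASTL had only 3 reads over the 3 controls and 268 over the libraries labelled knockout, a ratio of 87.1 after adjustment for TMM-scaled library sizes, with an exact 95% counting interval from 29.5 to 425.

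The desmosomal cadherin DSC3 fell from 27.6 ± 1.66 to 1.82 ± 0.239 CPM (SD, n = 3; log2 fold change -3.91, SE 0.12; adjusted p = 1.1e-06). SQLE, the squalene epoxidase of cholesterol synthesis, fell from 51.2 ± 12.3 to 7.28 ± 1.00 CPM. The glutamate transporter SLC1A3 fell from 30.03 ± 3.23 to 5.24 ± 0.235 CPM, and B3GALT5 from 38.7 ± 4.74 to 6.81 ± 0.899 CPM. C1orf106, the phosphodiesterase PDE4D, HOXA3, DACT1, MDGA1, ALDH1L2, the integrin ITGB8 and the adhesion molecule ICAM1 had log2 fold changes between -3.29 and -2.25.

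**Figure D2:**
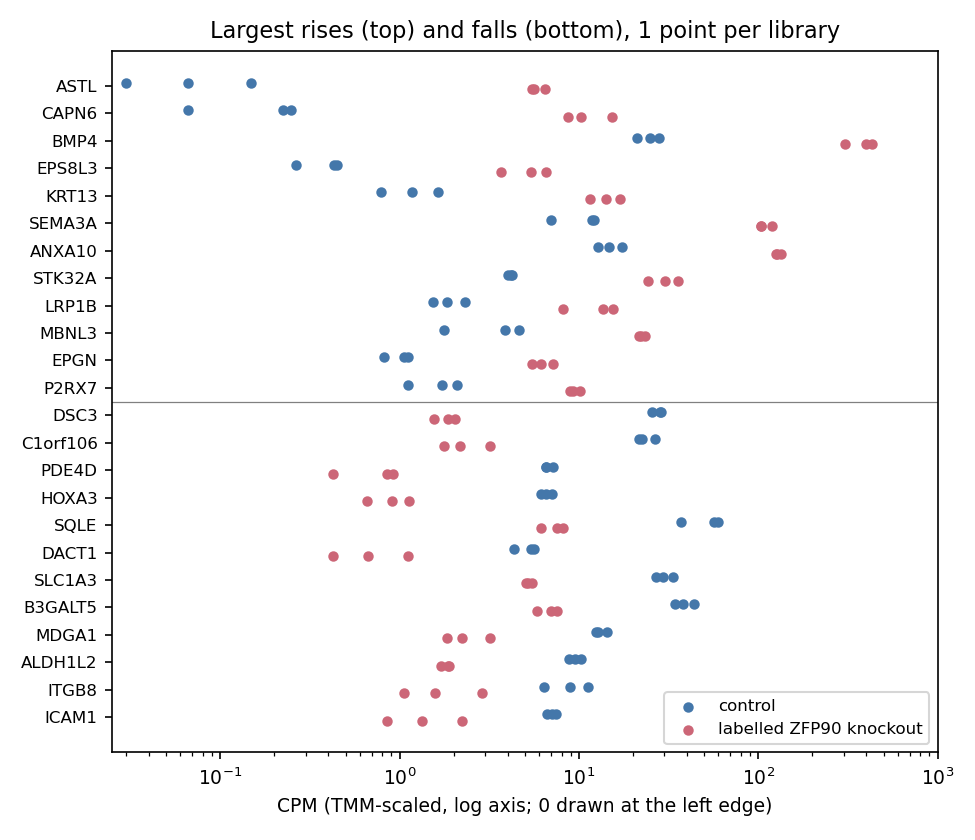
CPM (TMM-scaled, log axis) of the 12 largest rises and 12 largest falls, 1 point per library, with controls and libraries labelled ZFP90 knockout in separate colours. The groups do not overlap for any of these genes, which the naming rule required; BMP4 moves from 24.6 to 379 CPM and DSC3 from 27.6 to 1.82 CPM.

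Across the 16369 genes tested, 1593 were higher and 1861 lower in the libraries labelled knockout (edgeR, adjusted p under 0.05), and 205 and 320 of these by at least 2-fold. The groups did not overlap for 41.2% of all tested genes, where chance gives 10%. Scaling by library size alone called 986 higher and 2343 lower, so that 29.6% of calls were higher against 46.1%. The counts of higher and lower genes were 934 and 1236 without control replicate 1, 756 and 1025 without replicate 1 labelled knockout, and 793 and 1125 without replicate 3 labelled knockout. Leaving out control replicate 2 raised them to 2261 and 2361.

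Control replicate 2 had fewer reads than the other 2 controls on some chromosomes. It lay 0.026 to 0.061 above them in log2 on chromosomes 1 to 5 and 10 to 22. It then stood at 87.3% of the other controls on chromosome 6, 80.6% on 7, 75.1% on 8, 70.5% on 9 and 53% on X, and at 53.3% for the mitochondrial genome. Together with chromosome Y, these held 20.7% of the placed tested genes. There, chromosome Y included, 287 genes were called higher and 171 lower, against 431 and 472 without control replicate 2. Control means, SDs and fold changes of genes named from these chromosomes carry the deficit. Without control replicate 2, the log2 fold change of SQLE on chromosome 8 went from -2.81 to -2.99. That of SEMA3A on chromosome 7 went from 3.4 to 3.18.

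**Figure D3:**
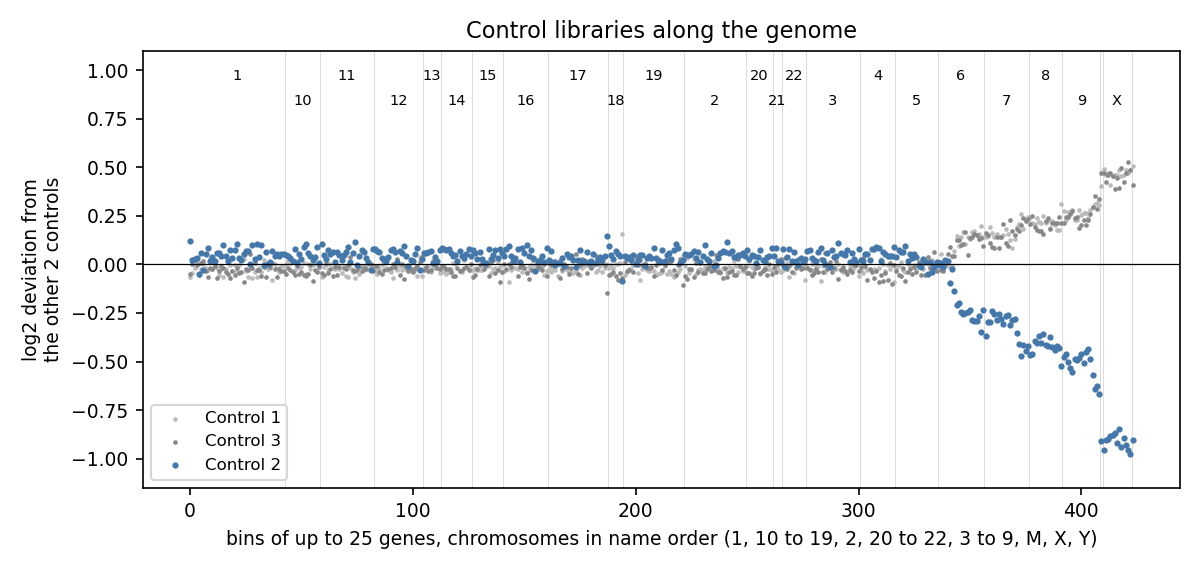
Median log2 deviation of each control library from the mean of the other 2 (vertical axis), in bins of up to 25 genes along the chromosomes in name order (horizontal axis). Control 2 is near 0 up to chromosome 5 and falls to -0.92 on X; Controls 1 and 3 rise there because control 2 is part of their reference.

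Of the 33 gene lists tested with camera, 6 were called, 4 upward and 2 downward. With an estimated correlation 0 were called by camera, where adjusted p was 0.115 or more and 2 lists had an unadjusted p under 0.05. In turn, fry called 7 lists, and camera on limma-voom values 3. At the preset correlation, 4 of the 10 splits of the libraries into 3 and 3, the labelled one included, called at least 6 lists. The highest other split called 9, so the number of lists called does not set the labelled groups apart. Counts of members below cover only listed genes that passed the count filter. For comparison, 21.1% of all genes tested were called in either direction, so counts near that share do not set a list apart. They are adjusted over all genes tested, followed by counts adjusted over the list alone. Many of them moved when 1 library was left out, and the larger moves are given beside the counts.

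The YAP target list fell: 9 of 19 members fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 4.16e-07; adjusted p = 0.115 with an estimated correlation). For this list fry gave an adjusted p of 0.00122, and camera on limma-voom values 7.01e-05. Tissue factor F3 fell by 1.79 on the log2 scale from 216 ± 20.7 CPM (SD, n = 3), NT5E by 0.97, the receptor kinase AXL by 0.77 and CRIM1 by 0.72. The neuronal genes repressed by REST also fell as a list, with 5 of 17 lower and 2 higher, also adjusted over the list alone (adjusted p = 0.00792; adjusted p = 0.514 with an estimated correlation). UNC13A fell by 1.14, SYT1 by 0.89 and the neuropeptide precursor VGF by 1.74, while CPLX1 rose by 0.78. This list's adjusted p was 0.00739 with fry and 0.157 with camera on limma-voom values. With camera on the 18 chromosomes where control replicate 2 showed no deficit, it was 0.0515.

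The mitosis list rose, with 15 of 28 members higher and 1 lower, and 19 and 2 adjusted over the list alone (camera adjusted p = 1.66e-06; adjusted p = 0.795 with an estimated correlation; 0.118 with fry). FOXM1, a transcription factor of the G2/M phase, rose by 0.91, AURKB by 0.75, the proliferation marker MKI67 by 0.64 and TPX2 by 0.47. Control replicate 2 had the highest mean of this list among the controls, 0.10 above the mean of all libraries in log2, where the other controls lay at -0.31 and -0.40. The libraries labelled knockout lay at 0.16, 0.33 and 0.12, so control replicate 2 came close to the lowest of them. Without control replicate 2, 26 members were higher and 2 lower, whereas 6 were higher without control replicate 1 or without replicate 1 or 2 labelled knockout, and 8 without control replicate 3 or replicate 3 labelled knockout; 0 to 2 were lower. Of 30 DNA replication genes, 4 rose and 1 fell (3 and 1 adjusted over the list alone), and 14 rose and 1 fell without control replicate 2, while 0 fell without control replicate 1 or replicate 1 or 2 labelled knockout; RRM2 rose by 1.00 and MCM7 by 0.43.

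The list of Wnt targets rose, with 4 of 13 higher and 2 lower, also adjusted over the list alone (adjusted p = 0.00613; adjusted p = 0.795 with an estimated correlation; 0.234 with limma-voom; 0.0657 with fry). Besides BMP4, the Wnt inhibitor DKK1 rose by 0.94 and the ubiquitin ligase RNF43 by 0.55, whereas cyclin D1 (CCND1) fell by 0.44. The TGF-beta and BMP target list rose, with 7 of 18 higher and 4 lower, and 8 and 4 adjusted over the list alone (adjusted p = 0.0388; adjusted p = 0.795 with an estimated correlation; 0.251 with limma-voom; 0.0795 with fry; 0.0524 without control replicate 1). ID3, an inhibitor of DNA binding, rose by 1.47, while LTBP3 fell by 0.90. BMP4 belongs to both lists, with a log2 fold change of 3.95. The median and mean were 0.196 and 0.458 for the Wnt list and 0.191 and 0.309 for the TGF-beta and BMP list. The 2 calls are therefore not independent, and neither list was tested without BMP4. With 1 library left out at a time, 3 to 4 Wnt targets were higher and 1 to 2 lower.

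The 13 mitochondrially encoded genes rose as a list (adjusted p = 0.00242; adjusted p = 0.795 with an estimated correlation; 0.156 with fry), with 2 higher over all genes tested and 9 adjusted over the list alone. Control replicate 2 held 4.77% of its gene reads in mitochondrial genes, the other controls 8.05% and 8.08%, and the libraries labelled knockout between 9.61% and 10.2%. The median log2 fold change of this list was 0.58 with all libraries and 0.34 without control replicate 2, where 12 of 13 were higher; 5 were higher without control replicate 3 and 1 without control replicate 1. The 2 calls over all genes, MT-ND1 and MT-ND6, did not hold when any 1 of the libraries labelled knockout was left out (edgeR adjusted p from 0.0703 to 0.134), and MT-ND1 did not hold without control replicate 1 (0.0608).

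**Figure D4:**
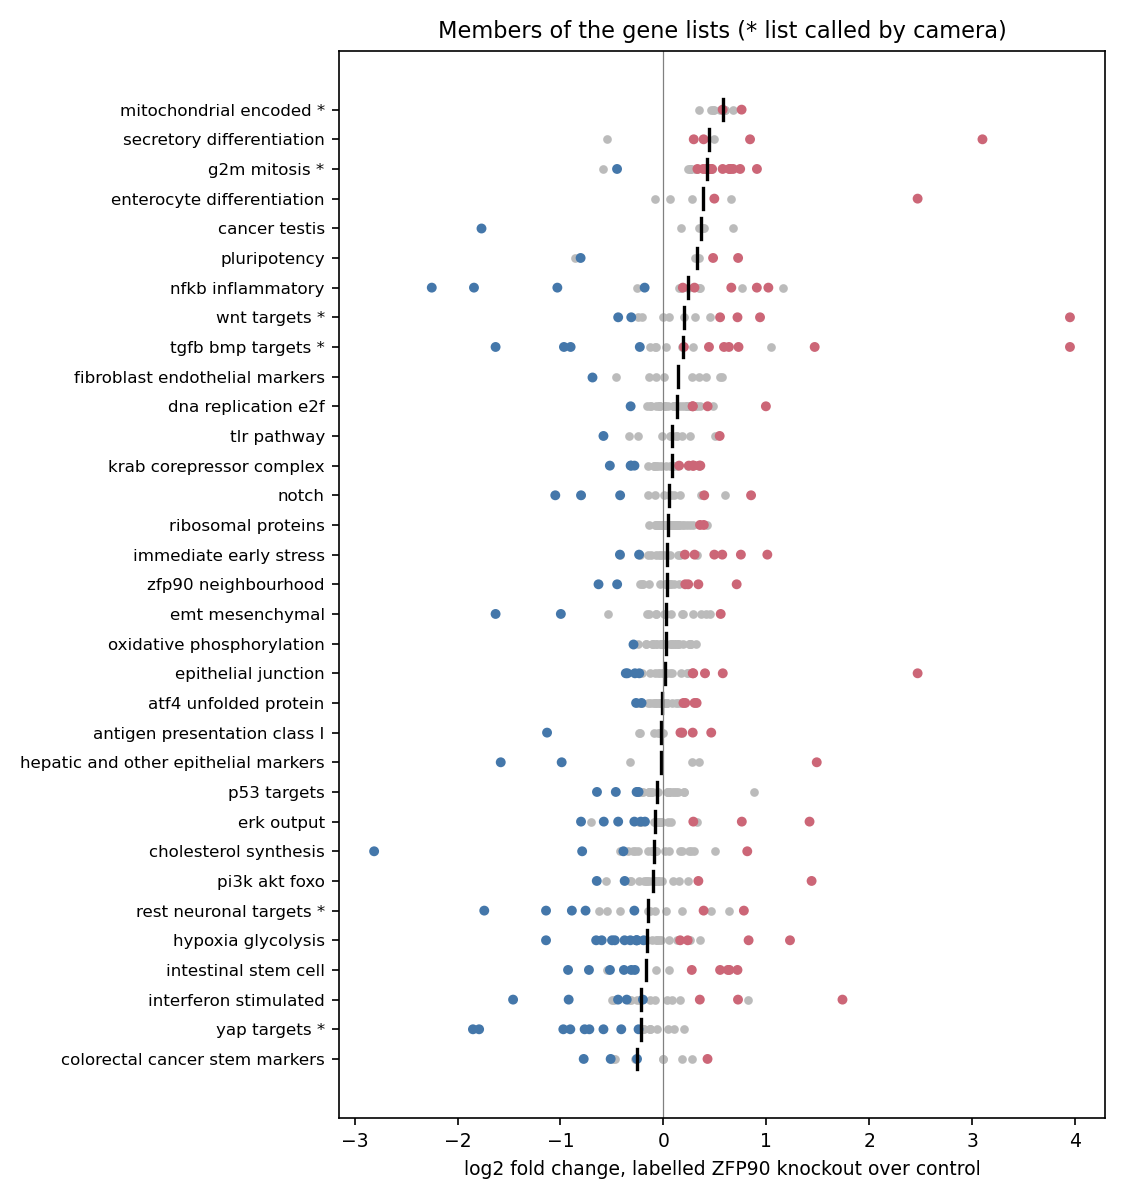
Log2 fold change (horizontal axis) of each tested member of the 33 lists with at least 5 members (vertical axis), with called members coloured by direction, other members grey and the median as a black line; an asterisk marks lists called by camera. YAP targets include 9 called falls and no called rise, and the mitosis list 15 called rises and 1 fall.

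The other 27 tested lists had camera adjusted p between 0.0508 and 0.985. Of 21 listed intestinal stem cell genes, 14 passed the count filter. Of these 14, 5 rose and 6 fell, also adjusted over the list alone. The stem cell transcription factor SOX9 fell by 0.93 and BMI1 by 0.72, while RNF43 rose by 0.55 and MEX3A by 0.64. Without replicate 1 labelled knockout the counts were 2 and 2; the lower count was also 2 without control replicate 1 and without replicate 2 labelled knockout. The higher count was 3 without replicate 3 labelled knockout, and the lower count was 4 without control replicate 3. Of 11 markers used for colorectal cancer stem cells, 1 rose and 3 fell, also adjusted over the list alone. This list was not called by camera (adjusted p = 0.144, and 0.795 with an estimated correlation), whereas fry called it downward (adjusted p = 0.0487). ALCAM fell by 0.77 and ITGA6 by 0.51, and PROM1, which encodes CD133, rose by 0.43. Of 15 listed pluripotency genes, only 6 passed the count filter. Of these 6, 2 rose and 1 fell (2 and 2 adjusted over the list alone), with KLF5 higher by 0.73. The pluripotency counts were 2 and 2 without control replicate 1, 1 and 0 without replicate 1 labelled knockout, and 1 and 1 without replicate 2 labelled knockout.

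Secretory and enterocyte genes were not called by camera (both adjusted p = 0.0508, and 0.514 with an estimated correlation), whereas fry called both upward (adjusted p = 0.00739 and 0.0265). Only 6 of 24 listed secretory genes and 6 of 26 listed enterocyte genes passed the count filter. Of these, 4 secretory genes rose and 0 fell, and 2 enterocyte genes rose and 0 fell, also adjusted over the list alone. The secretory count was 2 without control replicate 1 and without replicates 2 or 3 labelled knockout. The enterocyte keratin KRT20 rose by 2.48 and HNF4A by 0.50. Among 26 epithelial junction genes 5 rose and 4 fell (5 and 6 adjusted over the list alone), with OVOL1 higher by 0.58. The lower count ranged from 1 to 5 over the libraries left out in turn. It was 6 with control replicate 2 corrected along the genome. Of 17 mesenchymal genes, 1 rose and 2 fell, also adjusted over the list alone, with ZEB1 lower by 1.00 and COL6A1 higher by 0.56.

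Of 29 hypoxia and glycolysis genes, 4 rose and 11 fell (4 and 12 adjusted over the list alone), and fry called the list downward (adjusted p = 0.0439) where camera did not (adjusted p = 0.293, and 0.795 with an estimated correlation). The glucose transporter SLC2A1 rose by 1.23 and adrenomedullin (ADM) fell by 1.14. For cholesterol synthesis 1 of 24 rose and 3 fell (2 and 5). NF-kappa-B genes split, with 5 of 17 higher and 4 lower (7 and 4): NFKBIA rose by 0.91 and IL8 by 1.02, and ICAM1 fell by 2.25. Interferon-stimulated genes split as well, with 3 of 20 higher and 5 lower (4 and 6); OAS1 rose by 1.74 and IFIT1 fell by 1.46. Of 26 p53 targets, 0 rose and 4 fell (1 and 5), among them FAS, lower by 0.64. Of 24 ERK output genes 3 rose and 6 fell (4 and 9), with DUSP5 lower by 0.80 and EPHA4 higher by 1.42. Without control replicate 2 the counts higher and lower were 8 and 4 for NF-kappa-B genes, 5 and 6 for interferon-stimulated genes, 0 and 7 for p53 targets and 2 and 7 for cholesterol synthesis. Over the 6 libraries left out in turn, hypoxia genes ranged from 2 to 4 higher and 8 to 12 lower, interferon-stimulated genes from 2 to 5 and 2 to 6, ERK output genes from 2 to 4 and 4 to 8, and cholesterol synthesis from 0 to 2 and 2 to 7. With control replicate 2 corrected along the genome, hypoxia genes numbered 4 higher and 13 lower and interferon-stimulated genes 4 and 7. In that setting ERK output genes numbered 4 and 9, and cholesterol synthesis 3 and 7. The pairs in parentheses are adjusted over the list alone.

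Of 25 KRAB corepressor genes, 7 rose and 4 fell (7 and 5 adjusted over the list alone), with TRIM28, the corepressor bound by KRAB domains, higher by 0.29 and DNMT3A lower by 0.52. Of 23 PI3K and FOXO genes 2 rose and 2 fell (2 and 2), with SESN3 higher by 1.44 and IRS1 lower by 0.65. Of 20 immediate-early and stress genes 6 rose and 2 fell (7 and 2), of 27 ATF4 and unfolded protein genes 4 rose and 2 fell (5 and 3), of 15 Notch genes 2 rose and 3 fell (2 and 4), and of 14 class I antigen presentation genes 4 rose and 1 fell (4 and 1). Toll-like receptor genes numbered 1 higher and 1 lower of 13 (1 and 1), ribosomal proteins 2 and 0 of 42 (0 and 0), oxidative phosphorylation 0 and 1 of 29 (0 and 0), and cancer-testis genes 0 and 1 of 6 (0 and 1), the last being PRAME, lower by 1.77. Without control replicate 2, ribosomal proteins numbered 8 higher and 0 lower, oxidative phosphorylation 2 and 1, PI3K and FOXO genes 3 and 4, ATF4 genes 5 and 4, and Toll-like receptor genes 2 and 1. The oxidative phosphorylation fall was absent without control replicate 1 and without replicate 1 or 3 labelled knockout, and 2 fell without replicate 2 labelled knockout. The Toll-like receptor fall was absent without replicate 3 labelled knockout. Cancer-testis genes numbered 0 higher and 2 lower without control replicate 2 and without any 1 library labelled knockout. Over the 6 libraries left out in turn, class I genes ranged from 0 to 5 higher and 0 to 1 lower, immediate-early genes from 3 to 8 and 1 to 2, ATF4 genes from 1 to 5 and 1 to 4, Notch genes from 0 to 2 and 3 to 4, and ribosomal proteins from 0 to 8 higher. KRAB corepressor genes ranged from 4 to 8 higher and 2 to 4 lower, and PI3K and FOXO genes from 1 to 3 and 1 to 4. With control replicate 2 corrected along the genome, PI3K and FOXO genes numbered 3 higher and 5 lower, and ATF4 genes 5 and 7. The pairs in parentheses are adjusted over the list alone. The median, mean and test differed in sign for the Notch, class I, mesenchymal, cancer-testis and ATF4 lists.

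Of markers of other cell types, 2 of 19 for leukocytes passed the count filter, as did 10 of 16 for fibroblasts and endothelium and 6 of 17 for other epithelia. Of these, the leukocyte marker CD4 fell; 1 of 10 fibroblast and endothelial markers fell, and of 6 markers of other epithelia 1 rose and 2 fell (fry adjusted p = 0.0439 downward; camera adjusted p = 0.574, and 0.808 with an estimated correlation). Adjusted over the list alone, these were 1, 0, and 1 and 2. The fibroblast and endothelial call, ACTA2, was absent with each library left out and with DESeq2, where 0 fell. Of the other epithelia 1 fell with DESeq2 and with each library left out except control replicate 3, where 2 fell.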

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

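All alternatives were chosen before the data were examined except the correction of control replicate 2 along the genome and the restriction to 18 chromosomes. The ZFP90 rise held in every setting run, with log2 fold changes from 0.83 to 0.94. Library size alone gave 986 higher genes, and adjusted p under 0.01 gave 618 higher and 869 lower; the latter is fewer by construction. Lists called fell to 3 with limma-voom, for a cause that was not tested, and to 0 with an estimated correlation. That estimate was 0.909 for the mitosis list, 0.911 for the mitochondrial, 0.327 for the Wnt and 0.206 for the TGF-beta and BMP list. All 4 lie far above the preset 0.01, which overstates the evidence for these lists. For the YAP and REST lists it was -0.0174 and 0.0132. The YAP estimate lies below the preset, so a higher correlation did not remove the call of that list. Why the YAP and REST lists lost their calls was not tested further. Restricting to 18 chromosomes also dropped genes without a position and left 10863 of 16369 genes tested. By at least 2-fold, 134 were higher and 205 lower, fewer at least in part because fewer genes were tested. At any fold 1854 were higher and 1876 lower, more than with all genes, and 1053 of these calls were new. Calls outside the affected chromosomes thus also depended on which genes were in the fit. Leaving out or correcting control replicate 2 raised the counts as well. Whether its deficit is the cause was not tested. Leaving out 1 library at a time gave 756 to 2261 higher, 1025 to 2361 lower, 174 to 243 and 265 to 366 by at least 2-fold, 5 to 9 lists, and 0.85 to 0.94 for ZFP90. Without control replicate 2, 3316 of the 3454 calls were kept and 1306 were added; with its counts corrected, 2210 were higher and 2625 lower. Whether replicate numbers pair the libraries stays open. Same-number correlations were small, at 0.049, 0.14 and 0.093, but each library correlated best with its own number. That is a hint from the data and not the design. The replicate block gave 1623 higher, 1840 lower and 7 lists. DESeq2 called 1298 higher and 1524 lower and limma-voom 1653 and 1851; without a filter on low counts, 2252 and 2099 were called. Some uncalled neighbours of ZFP90 reversed sign near 0. Library size alone shifted the median of all genes from 0.00838 to -0.0582 by construction, and with it gave CDH1 -0.04261, CIRH1A -0.01933, COG8 -0.04714, PRMT7 -0.03595 and VPS4A -0.005927. Upper-quartile factors likewise shifted that median to -0.014 and gave COG8 -0.003406. Leaving out 1 library at a time gave COG8 from -0.01496 to 0.08271 and PRMT7 from -0.05371 to 0.1642; the cause was not tested. Depth limits the least abundant genes, such as ASTL with 3 control reads.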

Other observations

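The gene families in these 2 paragraphs, and all tests below except the counts over other splits of the libraries and the alternative scalings, were chosen after the results were seen. The p-values of the families, adjusted over these families alone, come from the values that picked them and cannot serve as support. HOX genes of the B cluster, transcription factors of body patterning, were lower in the libraries labelled knockout: 7 of 9 fell and 0 rose, with a median log2 fold change of -0.85 (camera adjusted p = 4.31e-09; adjusted p = 0.046 with an estimated correlation). In the A cluster 5 of 9 fell and 0 rose, with a median of -0.52 (adjusted p = 0.00016; adjusted p = 0.0974 with an estimated correlation), and in the C cluster 0 of 6 were called. These medians stayed negative under the 3 other scalings and without control replicate 2.

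Zinc-finger genes on chromosome 19 leaned upward, with 41 of 162 higher and 4 lower and a median of 0.20 (camera adjusted p = 1.5e-05; adjusted p = 0.046 with an estimated correlation). The median was 0.13 with library size only, and 29 were then higher. Zinc-finger genes elsewhere were called as well, with 41 of 261 higher and 15 lower and a median of 0.095 (camera adjusted p = 0.0114; adjusted p = 0.32 with an estimated correlation); the difference between both sets was not tested. Of 14 keratins 6 rose and 2 fell, and 2 of 3 metallothioneins fell. The 11 chromosome Y genes with enough reads had a median log2 fold change of 2.6, and 2.34 without control replicate 2, with 9 of 11 higher.

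The deficit of control replicate 2 followed the order of chromosome names. Over the 86 bins of chromosomes 6 to 9 and X, its deviation correlated with name order at a Spearman rho of -0.956, a correlation across bins, which are not independent replicates. This is consistent with reads missing towards the end of an alignment file sorted by chromosome name, an explanation found from the same values. Loss of nuclear chromosome copies is argued against by the mitochondrial genes, at -0.91 (SD 0.17 over genes), and GC content or transcript length by chromosome X, at -0.96 after a trend in both was removed. No other biological explanation was tested.

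ZFP90 RNA was higher in the libraries labelled knockout. A gain of the surrounding region is argued against by its 19 tested neighbours, with a median of 0.034 (SE 0.084) where a gain would need about the 0.90 of ZFP90; a gain of ZFP90 alone was not tested. The choice among the 4 scalings run is argued against by their lowest value, 0.83. These scalings differ little, with TMM factors from 0.9747 to 1.07, and a shift that all 4 miss was not tested. Group labels exchanged as a whole cannot be told apart from the labelled groups: in 3 of 3 libraries labelled knockout ZFP90 exceeded all controls, and no other value tells which group was edited. An effect of the editing on ZFP90 RNA itself stays open and untested.

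Neighbouring genes changed in the same direction more often than after shuffling. On the 18 chromosomes without the deficit of control replicate 2, 404 pairs of non-overlapping neighbours were called in the same direction, against a mean of 289 in 1000 shuffles within chromosomes (permutation p = 0.001, the smallest they can give), while pairs called in opposite directions numbered 220 against 274. This argues against overlapping genes as the whole source, and 373 pairs with different name stems, against a mean of 277, argue likewise against tandem paralogs. The 5 genes from RGS2 to CDC73 on chromosome 1 fell by log2 fold changes from -0.90 to -1.92. Cochran's Q test of equal changes across this run gave a p of 5.3e-20, so the 5 genes did not fall by 1 shared amount. The run was picked from these same values, and genes need not follow copy number equally. The test therefore cannot decide on a copy number change. A difference between the groups in copy number, chromatin or clone origin may remain, and was not tested. The chromosome Y genes also moved together, with 9 of 11 higher, 0 lower and a median log2 fold change of 2.6. These data cannot tell such a difference from an effect of the editing.

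The 6 libraries make only 10 splits into 3 and 3, too few for a share under 0.05. The labelled split called 3454 genes and the highest of the other splits 0, and 525 against 0 by at least 2-fold, so 1 split gave as many in each case. For gene lists the labelled split called 6 and the highest other split 9, and 4 of the 10 splits called as many as the labelled one.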
